A study of Mus musculus with 9 samples.

How the data were processed

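RNA levels were measured on 1-colour microarrays in mouse embryonic stem (ES) cells that lack Dgcr8, a protein needed to process microRNA precursors. Per the labels' protocols, the cells were transfected with 50 nM of a synthetic mimic of let-7c or of miR-294, or were mock transfected, then grown without leukaemia inhibitory factor (LIF) and harvested 12 h later. Each of the 3 groups had 3 biological replicates, so 9 arrays were compared. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols.

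The deposited table holds 1 value per probe set and array for 35557 probe sets. The submitters' processing notes name GCRMA, a method that corrects the background, normalizes the arrays and summarises the probes of a set; its version and settings are not given in the sources used here. The deposited values were taken as log2 intensities: their range is that of log2 values, while no header states the scale, so each log2 difference rests on that reading. The values were used as deposited with no further normalization. The array medians lay between 7.36 and 7.41. No pair of arrays had more than 0.0309% identical values, so no array appeared to be deposited more than once. The number of arrays limits the precision.

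Genes were named from GEO's annotation of the probe sets, and 21698 probe sets had their symbol matched through the gene ID to current RefSeq names, which changed 0 symbols; 91 kept the annotation's symbol. Of all probe sets, 21789 had 1 symbol, 1621 had several and 12147 had none. Genes were named only from probe sets with 1 symbol. For each of the 19938 genes so named, the probe set with the highest mean over the 9 arrays was used; 999 genes had several. A gene was tested if at least 3 arrays lay above their own array's 40th percentile of all probe sets. This kept 13182 genes (66.1%) and left out 6756 as dim. A gene above that percentile in the 3 arrays of 1 group alone was kept too, so a tested gene can be dim in the other groups. Among the genes called in a comparison, 1 in let-7c against mock, 9 in miR-294 against mock and 3 in let-7c against miR-294 had another probe set called in the opposite direction.

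Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend). A single fit of all 9 arrays had 3 group means and 6 residual degrees of freedom. The contrasts were let-7c minus mock, miR-294 minus mock and let-7c minus miR-294. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no minimum fold. All adjusted p-values for single genes come from this limma fit, all tests were two-sided, and ± after a difference is its standard error.

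The choices of gene lists, of test and design, of the rule for named genes and of the alternatives were made before the data were examined. The 29 lists covered known let-7 targets, known targets of the miR-290 family, pluripotency, Myc and Mycn with their partners, ribosome biogenesis, the G1 to S transition, its inhibitors, mitosis, microRNA biogenesis and silencing, p53 targets, interferon-stimulated genes, cholesterol synthesis and the stress response. They also covered early differentiation (epiblast and mesendoderm), neurectoderm, primitive endoderm, trophoblast, feeder fibroblasts, 2-cell-like cells, DNA methylation, Polycomb and trithorax factors, TGF-beta, Nodal and BMP signalling, epithelial-mesenchymal and adhesion genes, glycolysis, the respiratory chain, Ras-MAPK signalling, apoptosis, lysosomes and histones. Of 696 entries, 634 were matched to a gene and 573 were tested, and some genes are in several lists. The let-7 targets share 5 tested genes with the G1 to S transition, 4 with microRNA biogenesis and silencing and 2 with pluripotency. The miR-290 family targets share 3 with the inhibitors of that transition and 4 with TGF-beta, Nodal and BMP signalling. Shifts of these lists are therefore not fully separate from those of the targets. Cdkn1a, a published miR-290 family target, had no probe set of its own here and is not reported. Each list was tested against all other genes with camera (limma, preset correlation between genes of 0.01), adjusted over the 29 lists within a comparison. Camera with a correlation estimated per list and fry, which asks whether a list's genes move together on balance, were run as alternatives (with statmod 1.5.0). The known-target lists were written from general knowledge of published targets.

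Genes named in the text follow a fixed rule. In each comparison these are the 8 called genes with the largest rise and the 8 with the largest fall in which all arrays of one group lay above all of the other, leaving out predicted and clone names. Up to 4 called genes with the largest change are named per list. In the comparisons with mock, a fixed set was always named: Lin28a, Lin28b, Hmga2, Sall4, Myc, Mycn, Pou5f1, Sox2, Nanog, Rbl2, Lats2, Casp2, Tgfbr2 and Dgcr8. For the relation between the mimics, up to 6 genes with opposite calls were named in each direction. Members of small counts outside this rule are named too, and these, like the gene families grouped by symbol, were chosen after their values were seen.

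The planned tests of 3′ UTR seed matches to let-7c and miR-294, and of the rank of their seed heptamers, were not run, since no genome or UTR sequence was used here; the known-target lists stand in for them. The relation between the mimics was described by the covariance and correlation of their log2 differences from mock. Values for unchanged groups with shared mock arrays came from 100 draws, in which the mock arrays were simulated too. The arrays of a draw were independent, without the deviations that same-numbered arrays share.

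The fits were tested on simulated data with the spread of the real data and 13182 genes. In each comparison only 67, 67 and 66 genes were changed by a log2 of 0.25, 0.5 and 1. In the real data 28.7% or more of the genes were called, so the adjusted threshold was stricter in the simulation. Its recovery of small changes therefore does not measure recovery in the real data. In let-7c against mock, 44.8%, 97.0% and 100% of the genes changed by a log2 of 0.25, 0.5 and 1 were recovered, and 4 of 165 calls were false. In miR-294 against mock the shares were 43.3%, 85.1% and 100%, with 7 of 159 calls false. In let-7c against miR-294 they were 44.8%, 89.6% and 100%, with 13 of 169 calls false.

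Replicate numbers come from the sample titles, which say nothing about shared cultures or days. Same-numbered arrays deviated together from their group means in let-7c and mock (r across genes 0.133 to 0.418) and in miR-294 and mock (0.272 to 0.363), above the bound of 0.1 in each pair, but not in each pair of let-7c and miR-294 (0.0285 to 0.248). By this check the numbers paired the mimic arrays with the mock arrays. The fit without a replicate block stays the main one. A blocked value is given where it changes the call of a list or of a gene named by the rule.

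The alternatives were no filter and a stricter filter (60th percentile) on dim probe sets, quantile normalization, centring on each array's 75th percentile, an intensity trend with a robust prior, a fit of only the compared groups, a replicate block, every probe set tested, the mean of a gene's probe sets, a minimum log2 difference of 1 (0.5 for the relation), and leaving out each array in turn. Lists and the relation between the mimics were recomputed only with no filter, quantile normalization, a replicate block and each array left out, besides the list tests and the minimum difference named above. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.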

Results

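RNA was profiled in mouse ES cells without Dgcr8, which cannot make most of their own microRNAs, 12 h after transfection with a let-7c mimic, with a miR-294 mimic or without a mimic (mock). miR-294 belongs to the miR-290 family, which is abundant in normal ES cells, while let-7c belongs to a family that is abundant in differentiated cells. Each group had 3 arrays, and 13182 genes were tested. No group received a control mimic, so a difference from mock also holds any effect of transfected RNA as such. Arrays of a group correlated at 0.995 or above across the tested genes. The median standard deviation of a gene within a group was 0.0676 for let-7c, 0.0640 for miR-294 and 0.0566 for mock on the log2 scale. The probe set for Dgcr8 read 8.90 ± 0.04 with let-7c, 9.09 ± 0.03 with miR-294 and 9.01 ± 0.08 with mock (log2, SD, n = 3). The part of the gene that was deleted is not given in the sources used here, so this reading does not check the genotype. Dgcr8 did not pass the threshold against mock with let-7c (-0.11 ± 0.05, adjusted p = 0.12) or with miR-294 (0.08 ± 0.05, adjusted p = 0.26).

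The comparison of let-7c with mock asked which transcripts a let-7 microRNA lowers in these cells. Trim71, a stem cell RNA-binding protein and let-7 target, fell the most, from 10.85 ± 0.02 to 9.33 ± 0.09 (log2, SD, n = 3), a difference of -1.52 ± 0.05 (adjusted p = 4.66e-08). Sall4, a pluripotency transcription factor, fell from 10.92 ± 0.08 to 9.48 ± 0.06 (-1.44 ± 0.06, adjusted p = 9.49e-08). Dicer1, which encodes the enzyme that cuts microRNA precursors, fell from 11.09 ± 0.03 to 9.67 ± 0.06 (-1.42 ± 0.05, adjusted p = 4.66e-08). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose the most, from 10.77 ± 0.04 to 12.18 ± 0.13 (1.41 ± 0.07, adjusted p = 3.6e-07).

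Let-7c raised 1831 genes and lowered 1952, together 28.7% of those tested. Most changes were small, with median log2 differences of 0.25 and -0.26, and only 4 rises and 19 falls reached 2-fold. The further large falls were those of Trim6 (-1.48 ± 0.05), Arid3b (-1.33 ± 0.06), Igf2bp1 (-1.30 ± 0.05), Nr6a1 (-1.28 ± 0.06) and Prtg (-1.28 ± 0.11). Igf2bp1 encodes an oncofetal RNA-binding protein. The further large rises were those of Gpnmb (1.16 ± 0.09), the cystine transporter gene Slc7a11 (1.10 ± 0.12), Maff (1.05 ± 0.10), Flrt2 (0.99 ± 0.12), Lpar4 (0.99 ± 0.13), the BMP target Id1 (0.98 ± 0.08) and Ccn1 (0.97 ± 0.07).

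Among known let-7 targets, 27 of 34 tested genes fell and 1, Cdk6 (0.18), rose. Adjusted over the list alone, 29 fell and 1 rose. The list median was -0.61 (camera adjusted p = 3.4e-23). The list rests on published targets, some of which may have been found in these cells, so its counts are not fully independent evidence. Mycn fell (-1.16 ± 0.04, adjusted p = 4.87e-08), as did Lin28b (-0.69 ± 0.04, adjusted p = 3.07e-06), whose protein blocks let-7 maturation. Lin28a fell by less (-0.59 ± 0.15, adjusted p = 0.0138; 0.00242 to 0.0543 over the alternatives, the highest without let-7c replicate 1). Myc fell (-0.42 ± 0.11, adjusted p = 0.0191), a call that ended without let-7c replicate 1 (0.0603), without mock replicate 2 (0.0769) or with every probe set tested (0.0503; lowest over the alternatives 0.00197). Hmga2, an architectural chromatin protein gene, narrowly missed the threshold (-0.14 ± 0.05, adjusted p = 0.0503); it passed with a replicate block (0.0273), without let-7c replicate 1 (0.0329), without mock replicate 2 (0.0389), under quantile normalization (0.0411), with the stricter filter (0.0302) and with the mean of probe sets (0.0495), in a range of 0.0273 to 0.174 over the alternatives.

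Pluripotency genes were lower with let-7c, with 17 of 33 falling and 2, Lifr (0.16) and Stat3 (0.22), rising (19 and 3 adjusted over the list alone; median -0.20). The list had an adjusted p of 1.56e-05, and an adjusted p = 0.476 with an estimated correlation. Besides Sall4, the falls included Prdm14 (-0.67), the Polycomb partner Jarid2 (-0.54), Nanog (-0.46 ± 0.05, adjusted p = 5.1e-05) and Sox2 (-0.23 ± 0.05, adjusted p = 0.0043). Pou5f1, which encodes Oct4, did not pass the threshold (-0.10 ± 0.04, adjusted p = 0.0851), except with an intensity trend and robust prior (0.00785; up to 0.240 over the alternatives). Polycomb and trithorax factors were also lower (11 of 24 fell; 12 adjusted over the list alone; adjusted p = 0.00124 and, with an estimated correlation, 0.162), led by Smarcc1 (-0.62) and Cbx2 (-0.46), while Cbx7 (0.18) and Smarca2 (0.49) rose. Genes of microRNA biogenesis and silencing were lower, with 12 of 19 falling, the same count adjusted over the list alone (median -0.24, adjusted p = 1.56e-05; 0.162 with an estimated correlation). Tarbp2, a partner of Dicer1, fell by 0.86. The list shares 4 tested genes with the known let-7 targets: Dicer1, Lin28a, Lin28b and Trim71.

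Of 30 ribosome biogenesis genes, 25 fell with let-7c and 0 rose, and 25 fell adjusted over the list alone. Their median was -0.29 (adjusted p = 9.97e-16; adjusted p = 0.162 with an estimated correlation), with Bysl (-0.77), Rrp12 (-0.55), Polr1b (-0.48) and Ddx21 (-0.45) falling most. Of 33 genes of the G1 to S transition, 17 fell and only Cdk6 rose, also adjusted over the list alone (median -0.16, adjusted p = 1.13e-06; adjusted p = 0.476 with an estimated correlation). The replication licensing gene Cdc6 fell by 0.57, the phosphatase gene Cdc25a by 0.55, Rrm2 by 0.53 and Ccnd1, for cyclin D1, by 0.50. Cdc25a, Rrm2 and Ccnd1 are among the 5 tested genes that this list shares with the known let-7 targets. Ccnd1 was lower than mock with miR-294 too (10.20 to 10.34 per array, against 10.99 to 11.10 with mock). Inhibitors of the transition were slightly higher as a list (3 of 13 rose, 3 adjusted over the list alone; median 0.11; adjusted p = 0.0269, and 0.476 with an estimated correlation). Of these, Cdkn2b rose by 0.42 and Cdkn2d by 0.32. The call of that list ended without let-7c replicate 2 (0.0512), let-7c replicate 3 (0.0555) or mock replicate 1 (0.0611). Rbl2 (0.09 ± 0.09, adjusted p = 0.498) and Lats2 (0.20 ± 0.09, adjusted p = 0.126) did not pass the threshold, though Lats2 did with a replicate block (0.0331; up to 0.380 over the alternatives). Histone genes were lower, with 5 of 8 falling and 1, H1f2 (0.26), rising, also adjusted over the list alone (adjusted p = 0.0408; adjusted p = 0.476 with an estimated correlation). H1f1 fell most (-0.50), and the list's call ended without let-7c replicate 1 (0.104) or mock replicate 2 (0.0737).

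Lysosomal genes were higher with let-7c: 10 of 22 rose, led by Hexa (0.44), Ctsd (0.35) and Atp6v0d1 (0.31), and 2, Glb1 (-0.33) and Gla (-0.26), fell. Adjusted over the list alone 12 rose and 2 fell (median 0.15; adjusted p = 0.00909, and 0.63 with an estimated correlation). Epithelial-mesenchymal and adhesion genes were higher, with 7 of 22 rising, the same count adjusted over the list alone (median 0.25, adjusted p = 0.0194; 0.476 with an estimated correlation). They included the N-cadherin gene Cdh2 (0.55), Rhoc (0.52) and Snai2 (0.36). Cholesterol synthesis genes were higher, with 5 of 17 rising, led by Insig1 (0.49) and Stard4 (0.40), and 5 adjusted over the list alone (median 0.11, adjusted p = 0.0269; 0.671 with an estimated correlation). That call ended without let-7c replicate 2 (0.0910), let-7c replicate 3 (0.0555) or mock replicate 1 (0.153), and with fry (adjusted p = 0.109). The known miR-290 family targets were not called as a list with let-7c (median 0.09, adjusted p = 0.238): 6 rose, among them Tgfbr2 (0.43 ± 0.06, adjusted p = 0.000384), and 5 fell, among them Lefty1 (-1.17). Casp2 also fell (-0.15 ± 0.05, adjusted p = 0.0352), a call that ended without any 1 of the let-7c arrays (replicate 1, 0.0822; replicate 2, 0.0846; replicate 3, 0.0514) or of the mock arrays (replicate 1, 0.121; replicate 2, 0.0809; replicate 3, 0.05001; lowest over the alternatives 0.0197). It also ended with no filter (0.0748), under quantile normalization (0.0599) and with every probe set tested (0.0513). TGF-beta, Nodal and BMP genes were not called (adjusted p = 0.115) but passed without let-7c replicate 2 (0.0440) and with no filter on dim probe sets (0.0263). Interferon-stimulated genes (0.432), mitotic genes (0.312), Ras-MAPK genes (0.363) and early differentiation genes (0.905) were not called either.

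The comparison of miR-294 with mock asked which transcripts this microRNA lowers. Dazap2 fell the most, from 11.58 ± 0.03 to 9.22 ± 0.12 (log2, SD, n = 3), a difference of -2.36 ± 0.06 (adjusted p = 1.9e-09). Uchl1, for a ubiquitin hydrolase, fell from 10.96 ± 0.07 to 8.84 ± 0.10 (-2.12 ± 0.06, adjusted p = 4.43e-09). Casp2 (-1.20 ± 0.05, adjusted p = 3.04e-08), Rbl2 (-1.22 ± 0.09, adjusted p = 2.41e-06) and Lats2 (-1.16 ± 0.09, adjusted p = 3.63e-06), published targets of the family, all fell; Rbl2 encodes a retinoblastoma-like repressor and Lats2 a Hippo pathway kinase. Lin28a rose the most, from 8.57 ± 0.06 to 9.77 ± 0.35 (1.20 ± 0.15, adjusted p = 9.09e-05).

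MiR-294 raised 2735 genes and lowered 2786, together 41.9% of those tested. The median log2 differences were 0.24 and -0.31, and 4 rises but 93 falls reached 2-fold. The further large falls were those of Tbc1d8b (-2.11 ± 0.06), Tmem123 (-1.85 ± 0.05), Ankrd52 (-1.80 ± 0.06), Taf9b (-1.78 ± 0.06), the interferon-inducible GTPase gene Irgm1 (-1.54 ± 0.08) and Lefty1 (-1.54 ± 0.06), a Nodal antagonist. The further large rises were those of the mitochondrial import gene Tomm5 (1.16 ± 0.05), Rangrf (1.09 ± 0.04), Hmox1 (0.93 ± 0.07), the ES cell Ras gene Eras (0.86 ± 0.08), Lmo4 (0.86 ± 0.07), Nip7 (0.85 ± 0.06) and Timm8a1 (0.85 ± 0.06). Myc rose (0.80 ± 0.11, adjusted p = 0.000234), as did Sall4 (0.37 ± 0.06, adjusted p = 0.000364) and Mycn (0.19 ± 0.04, adjusted p = 0.00401). Lin28b fell slightly (-0.18 ± 0.04, adjusted p = 0.00658). Hmga2 (0.00 ± 0.05, adjusted p = 0.992), Pou5f1 (-0.02 ± 0.04, adjusted p = 0.681), Sox2 (0.01 ± 0.05, adjusted p = 0.881) and Nanog (-0.08 ± 0.05, adjusted p = 0.172) did not pass the threshold.

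Among known targets of the miR-290 family, 22 of 25 fell and 1, Dkk1 (0.14), rose, and the counts were the same adjusted over the list alone (median -0.67, adjusted p = 1.31e-13). As with the let-7 list, published targets may include some found in these cells. Ei24, a p53-induced gene, fell by 1.42, and Tgfbr2 fell by 0.33 (SE 0.06, adjusted p = 0.00118). Inhibitors of the G1 to S transition were lower, with 9 of 13 falling and 10 adjusted over the list alone (median -0.38, adjusted p = 6.96e-05; adjusted p = 0.282 with an estimated correlation). These included Tob1 (-1.10) and Rb1 (-0.71). The list shares 3 tested genes with the known miR-290 family targets, among them Rbl2 and Lats2. The genes that promote the transition were not called as a list (adjusted p = 0.817). Mitotic genes were lower, with 16 of 29 falling (18 adjusted over the list alone; median -0.18, adjusted p = 0.00118; adjusted p = 0.753 with an estimated correlation). Cdc25b (-0.78), Ect2 (-0.48), Anln (-0.44) and Kif23 (-0.41), the last 3 of them cytokinesis genes, fell most, while Aurka (0.21) and Birc5 (0.31) rose.

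Silencing factors themselves were lower with miR-294: Ago1 (-1.36), Tnrc6a (-1.08) and Tnrc6b (-0.74) led 11 of 19 genes of microRNA biogenesis and silencing that fell. In that list Lin28a, Tarbp2 (0.39), Trim71 (0.37) and Xpo5 (0.23) rose, and the counts were the same adjusted over the list alone (median -0.18, adjusted p = 0.0334; 0.573 with an estimated correlation). The list's call ended with a replicate block (0.0513), without miR-294 replicate 3 (0.0508) and without mock replicate 2 (0.0553). Interferon-stimulated genes were lower, with 8 of 16 falling and 8 adjusted over the list alone (median -0.14, adjusted p = 0.00628; 0.449 with an estimated correlation), led by Irf1, a transcription factor gene of the interferon response, and Xaf1 (-0.97), Ifi35 (-0.67) and Oasl2 (-0.66). In TGF-beta, Nodal and BMP signalling 10 of 24 genes fell, among them Lefty2 (-0.79), the receptor gene Tgfbr1 (-0.79) and Id1 (-0.60), and 4 rose: Bmp4 (0.43), Tdgf1 (0.23), Smad7 (0.21) and Nodal (0.20). These counts were the same adjusted over the list alone (median -0.10, adjusted p = 0.0413; 0.856 with an estimated correlation). That call ended with a replicate block (0.0579), without miR-294 replicate 1 (0.0543), without miR-294 replicate 3 (0.0583) and without mock replicate 2 (0.0847). Epithelial-mesenchymal and adhesion genes were lower, with 8 of 22 falling, also adjusted over the list alone (median -0.15, adjusted p = 0.011; 0.611 with an estimated correlation). Zeb1 fell by 0.78, Rhoc by 0.76, Vim by 0.67 and Cdh2 by 0.64.

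Ribosome biogenesis genes were higher with miR-294, with 25 of 30 rising and 0 falling, also adjusted over the list alone (median 0.35, adjusted p = 4.31e-11; adjusted p = 0.282 with an estimated correlation). Nip7 (0.85), Wdr74 (0.61), Nop16 (0.59) and Nhp2 (0.52) rose most. Ras-MAPK genes were higher, with 11 of 23 rising and 1, Sos1 (-0.90), falling, also adjusted over the list alone (median 0.15, adjusted p = 0.00644; 0.449 with an estimated correlation); Spry2 rose by 0.58 and Etv4 by 0.52. Of 33 pluripotency genes 16 rose, among them Nr5a2 (0.80), and 4 fell: Il6st (-1.07), Klf2 (-0.33), Fgf4 (-0.17) and Tfcp2l1 (-0.14). The counts were the same adjusted over the list alone (median 0.10, adjusted p = 0.0126; 0.753 with an estimated correlation). Early differentiation genes were higher, with 6 of 15 rising, also adjusted over the list alone (median 0.15, adjusted p = 0.0334; 0.488 with an estimated correlation), led by Evx1 (0.40), Dnmt3b (0.39), Eomes (0.35) and Cdx1 (0.35). That call ended without miR-294 replicate 3 (0.0722) or mock replicate 2 (0.0732). The known let-7 targets were not called (median -0.01, adjusted p = 0.828), with 11 rising and 10 falling; the sign of that median turned when arrays were centred on the 75th percentile. Polycomb and trithorax factors (0.675), lysosomal (0.372), cholesterol synthesis (0.4) and histone genes (0.817) were not called either.

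The direct comparison of let-7c with miR-294 asked which transcripts the mimics set apart. Dazap2 was higher with let-7c by 2.40 ± 0.06 (adjusted p = 1.74e-09), Tbc1d8b by 2.36 ± 0.06 and Uchl1 by 2.26 ± 0.06 (n = 3 per group). Trim71 was lower with let-7c (-1.89 ± 0.05, adjusted p = 2.12e-09), as were Sall4 (-1.81 ± 0.06) and Lin28a (-1.79 ± 0.15). The gene Hmox1, higher than mock with both mimics, was higher with let-7c than with miR-294 (0.47, adjusted p = 9.8e-05).

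With let-7c 3460 genes were higher and 3234 lower than with miR-294, together 50.8% of those tested. Of these 162 and 53 differed by at least 2-fold. Further genes far higher with let-7c were Tmem123 (1.89), Meioc (1.88), Hipk3 (1.85), Serpinb9b (1.84) and Pfn2 (1.81). Further genes far lower were Cdc34 (-1.49), Nr6a1 (-1.48), Rangrf (-1.47), Trim6 (-1.43) and Mycn (-1.35). Of 34 known let-7 targets, 26 were lower with let-7c and 3, Ccnd1 (0.26), Cdk6 (0.27) and Pbx3 (0.28), were higher (26 and 5 adjusted over the list alone; median -0.56, adjusted p = 3.92e-09; 0.0568 with an estimated correlation). Of 25 known miR-290 family targets, 21 were higher and 0 lower, also adjusted over the list alone (median 0.66, adjusted p = 7.93e-11; 0.0568 with an estimated correlation).

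All 30 ribosome biogenesis genes were lower with let-7c than with miR-294, also adjusted over the list alone (median -0.66, adjusted p = 8.26e-17; 0.115 with an estimated correlation), with Bysl at -1.13 and Wdr74 at -0.98. Of 33 pluripotency genes, 26 were lower and 4 higher, also adjusted over the list alone (median -0.37, adjusted p = 1.68e-06; 0.385 with an estimated correlation); the 4 were Il6st (0.93), Stat3 (0.25), Klf2 (0.24) and Lifr (0.16). Of 33 genes of the G1 to S transition 17 were lower, led by Cdc25a (-0.91), Orc1 (-0.85) and Cdc6 (-0.68). In that list Rrm1 (0.30), Pola1 (0.29), E2f1 (0.28), Cdk6 and Ccnd1 were higher, also adjusted over the list alone (median -0.17, adjusted p = 0.00321; 0.594 with an estimated correlation). Inhibitors of the transition were higher in 11 of 13 genes, also adjusted over the list alone (median 0.46, adjusted p = 8.56e-06; 0.129 with an estimated correlation), led by Lats2 (1.36), Rbl2 (1.31) and Tob1 (1.20). Epithelial-mesenchymal and adhesion genes were higher in 15 of 22, or 16 adjusted over the list alone (median 0.37, adjusted p = 0.000612; 0.385 with an estimated correlation), with Rhoc (1.28), Cdh2 (1.19) and Zeb1 (0.81) among them. Lysosomal genes were higher in 16 of 22 and lower in 4, or 17 and 4 adjusted over the list alone (median 0.21, adjusted p = 0.00606; 0.62 with an estimated correlation). The lysosomal membrane gene Lamp2 differed most (1.41), and Gla (-0.34), Glb1 (-0.22), Npc1 (-0.16) and Ctsz (-0.14) were lower. Interferon-stimulated genes were higher in 10 of 16, or 11 adjusted over the list alone, with Irf1 (1.06) and Cxcl10 (1.02) in the lead; Oas1a (-0.35) and Trim25 (-0.25) were lower (median 0.21, adjusted p = 0.00554; 0.385 with an estimated correlation). Mitotic genes (adjusted p = 0.0611), histone genes (0.0694) and the respiratory chain (0.0913) were not called, but they passed without let-7c replicate 1 (0.0145), without let-7c replicate 2 (0.0436) and without miR-294 replicate 3 (0.0458) respectively. Mitotic genes also passed under quantile normalization (0.00302) and with no filter on dim probe sets (0.0147), and histone genes with no filter (0.0318). Genes of microRNA biogenesis (0.579), TGF-beta signalling (0.858), Ras-MAPK signalling (0.154), Polycomb and trithorax factors (0.0913), cholesterol synthesis (0.507) and early differentiation (0.131) were not called.

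Across the comparisons 11, 11 and 9 lists were called, of which 1, 1 and 0 held with an estimated correlation: the let-7 targets with let-7c (adjusted p = 0.00868) and the miR-290 family targets with miR-294 (adjusted p = 0.04). Lists for apoptosis, DNA methylation, glycolysis, Myc and Mycn with their partners, neurectoderm, the respiratory chain, p53 targets, the stress response and 2-cell-like cells were called in none of the comparisons. The markers of primitive endoderm, trophoblast and feeder fibroblasts were not called either, and adjusted p-values over all these lists lay between 0.0913 and 0.951. With no filter on dim probe sets, DNA methylation passed in let-7c against mock (0.0272) and apoptosis in the direct comparison (0.0422).

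Several genes changed in opposite directions against mock. Trim71, Sall4 and Lin28a fell with let-7c and rose with miR-294. Cdc34, for a ubiquitin-conjugating enzyme, fell with let-7c (-1.13) and rose with miR-294 (0.36), and Rangrf did the same (-0.38 and 1.09). Nr6a1 rose by 0.20 with miR-294, a call that ended without miR-294 replicate 2 (0.0801), miR-294 replicate 3 (0.0554), mock replicate 2 (0.0740) or mock replicate 3 (0.104; lowest over the alternatives 0.00450). In the other direction, Meioc rose with let-7c (0.64) and fell with miR-294 (-1.24), as did Hipk3 (0.39 and -1.45), Serpinb9b (0.63 and -1.21), Pfn2 (0.46 and -1.35) and Marchf8 (0.44 and -1.32). Tbc1d8b rose by 0.25 with let-7c, but not without let-7c replicate 2 (adjusted p = 0.0530; lowest over the alternatives 0.00597).

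**Figure D1:**
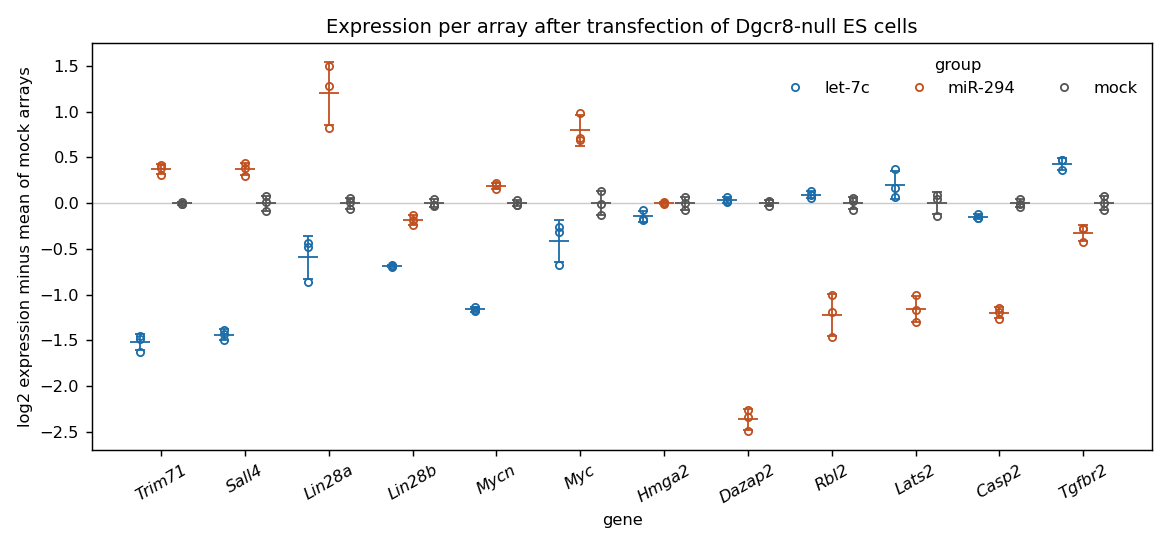
Genes lie along the x axis with the groups side by side, a point per array, a horizontal mark at the group mean and bars of 1 SD. The y axis is the log2 value minus the mean of the mock arrays. Trim71 lies 1.52 below mock with let-7c and 0.37 above it with miR-294, and Dazap2 lies 2.36 below mock with miR-294.

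Over all tested genes, 588 fell with let-7c and rose with miR-294 (405.0 for independent lists), and 535 rose with let-7c and fell with miR-294 (387 for independent lists). In the same direction, 419 rose with both (379.9 for independent lists) and 473 fell with both (413 for independent lists). Both comparisons use the same residual spread of each gene, so a gene with a small spread is called more readily in both, whatever its directions. Independent lists may thus be too low a base for each class, also for opposite directions. Unchanged groups simulated with shared mock arrays gave 0 genes in each class. That was fixed in advance, since groups without change give almost no calls. The mock arrays cannot be split into parts of 2, and the shared controls move both differences the same way. Part of the excess in the same direction may thus come from these controls. Without a control mimic, a common effect of transfected RNA cannot be told apart either. The log2 differences of the mimics had a correlation of -0.0408 across genes, which are not independent replicates. It lay between -0.0688 and -0.00388 with 1 array left out, and same-numbered differences gave 0.0433, 0.0173 and -0.0528. Simulated unchanged groups, whose arrays were drawn as independent, gave 0.5004. That value follows from the shared controls alone where no gene changes, so it is no benchmark for data with many changed genes. The covariance of the mimics' differences was -0.00214 against 0.00257 simulated, a difference of -0.00471 beyond the shared controls (-0.00407 with a replicate block).

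**Figure D2:**
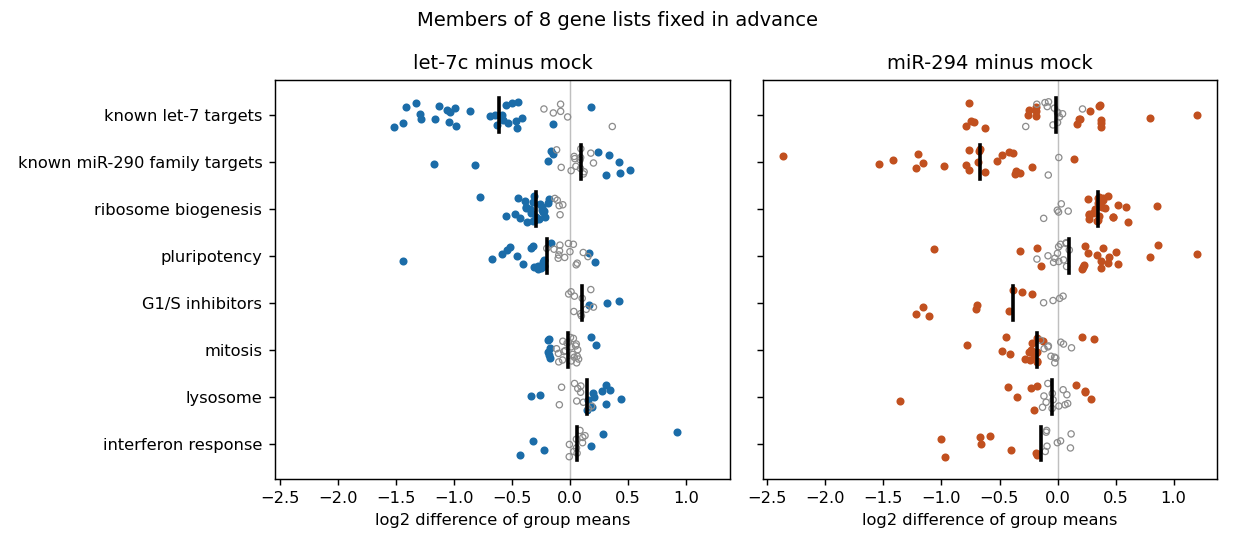
Log2 differences from mock of the genes in 8 lists, with let-7c in one panel and miR-294 in the other; filled points passed the threshold, open grey points did not, and the black line is the list median. Ribosome biogenesis has a median of -0.29 with let-7c and 0.35 with miR-294, and both medians keep their sign under quantile normalization and under centring on the 75th percentile.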

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

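The tests of the ribosome biogenesis list in this part were set before they were run, but the directions of its medians were already known. The lists named here were flagged because the mimics moved them in opposite directions against mock, and the direct comparison of let-7c with miR-294 gives the size of the difference. It uses the same values that picked the lists, so it is not independent evidence.

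Ribosome biogenesis genes had a median log2 difference of -0.66 between let-7c and miR-294 (adjusted p = 8.26e-17; 0.115 with an estimated correlation), lying below mock with let-7c (-0.29) and above it with miR-294 (0.35). A normalization effect tied to expression level is argued against: of 10000 random lists matched on mean expression, 0 had a median as far from 0 in either comparison (central 95% from -0.11 to 0.02 and from -0.06 to 0.09). Differences between replicate numbers are not decided by the planned test, in which 6 of 6 differences between same-numbered mimic and mock arrays had the direction of the pattern: each group holds each number once, so number effects common to the groups cancel by design. An effect of the mimics on growth, with Mycn (-1.16) and Myc (-0.42) lower with let-7c and higher with miR-294 (0.19 and 0.80), is a candidate explanation that was not tested. A technical factor that follows the groups stays open too.

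Pluripotency genes had a median difference of -0.37 between let-7c and miR-294, with a median of -0.20 against mock for let-7c and 0.10 for miR-294. Inhibitors of the G1 to S transition, a list that shares 3 tested genes with the known miR-290 family targets, differed by 0.46. Their medians against mock were 0.11 and -0.38. Epithelial-mesenchymal and adhesion genes differed by 0.37, with medians of 0.25 and -0.15 against mock. These medians kept their sign under quantile normalization and under centring on the 75th percentile. No explanation was tested for these lists.

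Probe sets without a gene name, which the comparisons above leave out, also changed. Fitted with all probe sets, 698 of 6499 such probe sets (10.7%) passed the threshold in let-7c against mock, 284 higher and 414 lower. In miR-294 against mock 1229 passed (18.9%), 731 higher and 498 lower. Among probe sets with a name the shares were 22.4% and 35.4%. What these probe sets measure is not analysed here.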

How the results depend on the processing

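Only lists and genes named by the fixed rule were followed over the alternatives, not the genes named outside it. None of these that was called, as reported or in an alternative, reversed direction under any alternative run. For genes, many settings could not do so. The filters, the trend, the fit of only the compared groups, the block and the test of every probe set leave a named gene's log2 difference unchanged. Only quantile normalization, centring, the mean of probe sets and leaving out an array of a compared group could reverse it. Medians of some lists without a call changed sign. Leaving aside a minimum difference, 97 genes named by the rule (78.9%) in let-7c against mock stayed on the same side of the threshold in every setting. So did 116 (92.1%) in miR-294 against mock and 109 (94.8%) in let-7c against miR-294. Lists and the relation between the mimics were rerun in fewer settings: no filter, quantile normalization, a replicate block and each array left out. Over these, 24, 26 and 25 of the 29 lists stayed on the same side. With an estimated correlation 1, 1 and 0 lists were called in place of 11, 11 and 9; with fry, which does not compare a list with other genes, 15, 15 and 24 were.

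Requiring a log2 difference of at least 1 cut the calls by construction to 4 higher and 19 lower with let-7c against mock, 4 and 93 with miR-294, and 162 and 53 in let-7c against miR-294. Requiring at least 0.5 left 5 genes higher with both mimics, 15 lower with both, 5 lower with let-7c and higher with miR-294, and 20 the other way. The other settings kept each count of changed genes within a single comparison within 1.5 times. The correlation of the mimics was 0.0197 with no filter on dim probe sets; the cause was not tested. The covariance beyond the shared controls stayed below 0 in each setting run for it.

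Leaving out 1 array at a time, let-7c raised 1294 to 1866 genes and lowered 1396 to 1953. MiR-294 raised 2172 to 2864 and lowered 2333 to 2866. In the direct comparison 3059 to 3426 were higher and 2921 to 3172 lower. Genes higher with both mimics numbered 244 to 386 and genes lower with both 275 to 462, each lowest without mock replicate 2. Genes higher with let-7c and lower with miR-294 numbered 354 to 567, lowest without mock replicate 3. Fewer arrays lower the power of these fits. Without mock replicate 2, 2625 of the 3783 genes called with let-7c (69.4%) and 4421 of the 5521 called with miR-294 were called again; without miR-294 replicate 2, 5881 of 6694 were in the direct comparison. These were the lowest counts of shared calls over the settings that test the same genes, leaving aside the minimum difference.

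With replicate numbers as a block, 2272 genes were higher and 2285 lower in let-7c against mock, 3089 and 3096 in miR-294 against mock, and 3731 and 3500 in the direct comparison. In miR-294 against mock the block ended the calls of microRNA biogenesis and silencing (0.0513) and of TGF-beta, Nodal and BMP signalling (0.0579). Among genes named by the rule the block brought Hmga2 and Lats2 past the threshold in let-7c against mock. It took Evx1 out of the direct comparison (0.0542). It changed no other call of a list or of a gene named by the rule.

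The seed match and seed heptamer tests, with their alternatives, were not run, since no genome was used here. Dim genes set a limit: 6756 genes lay too low to be tested. In the simulation, changes of 0.25 on the log2 scale were recovered in under 45% of genes. Far fewer genes changed there than were called in the real data, so that share is not the recovery of the real fits.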

Other observations

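The gene families below were grouped by symbol after the data had been seen. The tests of the interferon response, of snoRNA host genes and of other splits of the arrays, and the list of Nrf2 targets, were also chosen only then.

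Other splits of the 6 arrays in each comparison were fitted with limma. The real split was the 1 split of 10 with as many calls in let-7c against mock (3672), in miR-294 against mock (5559) and in let-7c against miR-294 (6355). The highest count in any other split was 0, also in splits that part all 3 pairs of same-numbered arrays. Each other split mixes arrays of both groups, so genes that differ between the groups widen its spread. Few calls in these splits are thus given by design and do not measure false calls. At an unadjusted p under 0.05 the other splits gave at most 466, 380 and 282 genes, against 5295, 6674 and 7092. With 10 splits a share under 0.05 cannot be reached.

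Small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, were higher with miR-294: 45 of 50 rose and 0 fell, with a median of 0.40. The family was called against other genes (camera adjusted p = 2.13e-14), but not with an estimated correlation (0.121). Snora74a (0.83) and Snora75 (0.79) rose most. With let-7c 20 fell and 0 rose (median -0.16, adjusted p = 0.000216; 0.342 with an estimated correlation). The median kept its sign in both comparisons under quantile normalization and centring on the 75th percentile.

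Most snoRNAs are cut from introns of host genes, so that signal from the host transcript is a candidate explanation. Over 23 host genes with 27 of the snoRNAs, the Spearman correlation of host and snoRNA differences between let-7c and miR-294 was -0.103 (permutation p = 0.639, bootstrap interval -0.486 to 0.302), which leaves the question open. The snoRNA minus host difference, added as a criterion after the medians had been seen, had a median of -0.28 (-0.62 to -0.18), so the hosts moved less than their snoRNAs. In the snoRNA median the lowest miR-294 array lay 0.445 above the highest let-7c array, while the widest range within a group was 0.117. The family was picked after the values of these same arrays had been seen. This gap therefore cannot decide on chance differences in short RNA recovery between arrays. A recovery difference that follows the groups stays open.

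Hmox1 was higher than mock with both mimics (1.41 and 0.93). An interferon response to the transfected RNA would raise interferon-stimulated genes. With miR-294 the tested genes did not rise: 0 of 16 rose and 8 fell (median -0.14, bootstrap interval -0.582 to -0.0479). That interval treats genes as independent, and camera with an estimated correlation gave an adjusted p of 0.449. A further 9 genes of the list were too dim to test, and Irf1 itself fell with miR-294. An interferon response is thus not excluded with miR-294, and it stays open with let-7c (0.0587, -0.00498 to 0.110). With let-7c, Cxcl10, Ddx58 and Psmb8 rose, and Trim25, Rsad2 and Oas1a fell, the last with adjusted p-values up to 0.113 over the alternatives. An oxidative stress response through Nrf2 would raise its other targets, and 22 of these were tested, without Hmox1 and Slc7a11: with let-7c their median was 0.12 (7 rose and 2, Gsr and Ftl1, fell), where limma's camera gave 0.00327 as its p-value (0.176 with an estimated correlation). With miR-294 their median was -0.06 (interval -0.126 to 0.0168), camera gave 0.0995, and 7 fell while 2, Fth1 and Taldo1, rose; both p-values are unadjusted, as this list was tested alone. Whether Nrf2 activity accounts for part of the change thus stays open with both mimics. With let-7c the list was higher only with the preset correlation between genes. With miR-294 an Nrf2 response cannot be told apart from other causes, since the interval includes 0.

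Further families moved, in each case only with the preset correlation. With miR-294, 54 of 77 mitochondrial ribosomal protein genes rose and 4, Mrpl30, Mrpl32, Mrpl41 and Mrps22, fell (median 0.22; adjusted p = 0.121 with an estimated correlation), 16 of 23 mitochondrial import genes rose (0.26; 0.129) and 17 of 27 RNA polymerase subunit genes rose (0.25; 0.150), while Polr2a, Polr3f and Polr3gl fell. With let-7c 10 of the RNA polymerase subunit genes fell and 2, Polr1d and Polr2d, rose (-0.07; 0.342). Kinesin genes fell with miR-294 in 22 of 32 (-0.21; 0.121), while Kif6 and Kif7 rose, and 4 of 5 interferon-inducible GTPase genes fell (-0.62; 0.150): Irgm1, Gbp4 (-1.20), Gbp7 (-0.62) and Gbp2b (-0.58). With let-7c, 14 of 31 tRNA synthetase genes fell (-0.13; 0.342), while with miR-294 15 rose and 2, Iars2 and Wars2, fell (0.12; 0.212). Also with let-7c, 9 of 18 vacuolar ATPase genes rose (0.16; 0.342), while Atp6v0a4 and Atp6v1b2 fell. Hairpin precursors of microRNAs were not called with miR-294 (median 0.04, adjusted p = 0.255).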
